A study of Arabidopsis thaliana with 6 samples.

How the data were processed

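Total RNA of 8-day-old Arabidopsis thaliana seedlings of the Columbia-0 background was hybridised to Affymetrix ATH1 arrays, 1 array per sample. The 6 arrays fall into 2 groups, the lib mutant and the wild type, with 3 arrays each that the labels call biological replicates. Per the labels' protocols, the plants grew on vertical agar plates with 1% sucrose under 16 h of light and 8 h of dark, and received no treatment. The labels do not give the tissue in one way: the labels of the samples name whole seedlings, whereas the design text of the series names roots. This was not settled here.

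The deposited table of array values holds log2 signals, made by the authors with MAS5 per the submitters' processing notes (version not given in the sources used here). MAS5 turns the probes of a probe set into 1 signal per array, and it leaves a wide scatter among dim probe sets. On the linear scale the deposited log2 values have a 2% trimmed mean of 496 on each of the 6 arrays, so the arrays had been scaled to a common level, and between 405 and 734 probe sets per array stand at the lowest value, a log2 of 0 (a signal of 1). These values were used as deposited, with no further normalization. The table holds 22746 probe sets and no Affymetrix control probe sets. A second deposited table gives, per probe set, a p-value and a ratio of lib to wild type from the authors. Each of the 22746 deposited p-values equals, within 1e-06, an unadjusted two-sided unequal-variance comparison of the log2 values recomputed from the arrays, and each deposited fold equals, within a relative 1e-06, the ratio of the mean linear signals. The design text speaks of a corrected p below 0.05 together with a 2-fold change.

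Probe sets were named through the platform annotation, with symbols updated through gene identifiers of the TAIR10.1 gene table. In that annotation 13513 probe sets had 1 gene, 503 had several and 8730 had none, and 13436 probe sets could be tied to the locus of 13286 genes. Probe sets with several genes were tested and counted but never named. Of the 144 genes with more than 1 probe set, 122 had the same outcome on each, 21 were called on part of them and 1 was called in opposite directions. None of these 144 genes is among the named genes or the members of the lists.

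The comparison of lib with wild type was fitted to all probe sets with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, 2-sided), and p-values were adjusted by the Benjamini-Hochberg method. An adjusted p under 0.05 was called a change, and calls with a fitted fold of at least 2 were counted separately. Fold changes are log2 differences, lib minus wild type, with their standard error (SE). With 3 arrays per group, the number of arrays limits the precision.

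The groups, the tests, 21 gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The rule named OMR1, and the 10 largest rises and 10 largest falls among probe sets of exactly 1 gene with an adjusted p under 0.05, a 2-fold change, no overlap between the arrays of the groups, and a higher group mean above the median of all probe sets; 415 probe sets met it. In each list it named the 4 members of smallest p, or all members for branched-chain amino acid synthesis and aliphatic glucosinolate synthesis. Genes named outside this rule were chosen after their values were seen, and the text says so. The annotation tied 61 of the 366 genes in the 21 lists to a probe set of their own, and only such genes are called measured here. The others may still be on the array, among the 8730 probe sets without a gene or the 503 with several. Lists of at least 3 measured genes were tested with limma's camera at a preset correlation of 0.01, on the brightest probe set of each gene and adjusted over the 11 lists tested. The test was repeated with an estimated correlation, and fry was run beside it. A further 6 lists were added once the coverage of the annotation was known and before any model was fitted. The genes of the chloroplast chromosome were added as a list after the data were seen, and these 7 lists were adjusted among themselves. Also after the data were seen, 34 families of at least 7 genes that share the opening letters of their symbol were tested in the same way.

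Alternatives were eBayes without the intensity trend, quantile normalization, centring each array on its median, log2(signal + 16), only the probe sets with a mean above the median, the replicate number as a block, array weights, an adjusted p under 0.01, each array left out in turn, and for the lists other choices of probe set, correlation, ranking and background. A filter on detection calls was planned and not run, because detection p-values were not used here. OMR1, which encodes threonine deaminase, has no probe set of its own in the annotation and was not analysed here. The lists of nitrogen assimilation, amino acid transporters, salicylate and pathogen defence, and seed storage were not analysed here. The annotation tied none of their members to a probe set of its own.

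The fit was tested on simulated data for lib against wild type, with 22746 probe sets of which 200 were changed. It recovered 20% of those changed by a log2 of 0.5, 70% at 1, 92% at 2 and 60% at -1, and 4.72% of its 127 calls were false. All 200 were placed among probe sets at or above the median signal, so recovery among dimmer ones was not covered. They are also a far smaller share than the 20.7% called in the real comparison, so these rates need not hold there. In simulated list tests a list of 12 genes shifted by a log2 of 0.8 was called, and 0 of 20 unshifted lists were. The simulated noise was independent between genes, so these tests do not cover lists whose genes vary together.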

Results

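Transcript levels of the Arabidopsis lib mutant and its wild type were measured on 6 ATH1 arrays, 3 per genotype, from 8-day-old plants. The title of the series places the mutant in the context of a limited isoleucine supply and asks about the metabolism of branched-chain amino acids and of glucosinolates, the sulfur-rich defence compounds of the Brassicaceae. The median log2 signal per array lay between 7.40 and 7.52. Arrays of one genotype resembled each other more than arrays of the other genotype: the median Spearman correlation of an array across probe sets was 0.980 to 0.984 within its own group and 0.963 to 0.970 with the other group. Replicate 3 of lib stood somewhat apart and received the lowest array weight, 0.507, against 2.41 for lib replicate 1. The sample labels name whole seedlings and the design text names roots, so the tissue behind the values below is not settled. The shoot markers PRK and SBPASE had signals of 25.3 to 79.7, RCA of 309 to 772 and LHCB4.1 of 730 to 1718. Of the root markers, EXPA7 had signals of 431 to 713, EXPA18 of 782 to 1189 and PYK10 of 11847 to 20685. Levels of different probe sets cannot be compared directly, so these signals alone do not settle the tissue.

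The largest rise in lib was that of NDB4, which encodes an external NAD(P)H dehydrogenase of mitochondria. Its signal was 1.72 to 7.04 on the wild type arrays and 238 to 357 on the lib arrays, a log2 fold change of 6.41 (SE 0.52, adjusted p = 0.000150). AT2G04050, a member of the MATE efflux family, rose by 4.14 (SE 0.29), AT2G41730, on a probe set of the type that can cross-hybridise, by 3.69 (SE 0.15) and AT2G21640, known for its response to oxidative stress, by 2.81 (SE 0.22). BCAT4, the aminotransferase that opens the chain elongation of methionine for aliphatic glucosinolates, rose by 2.86 (SE 0.26), from a mean log2 signal of 9.25 ± 0.66 (SD, n = 3) to 12.11 ± 0.03 (SD, n = 3). The remaining named rises were AT5G47600 at 2.97, AT2G43660 at 2.75, AT5G60520 at 2.44, AT3G28500 (an acidic ribosomal protein of the P2 type) at 2.24 and AT3G09700 (a protein with a DnaJ domain) at 2.18. The wild type signals of NDB4 and of AT2G04050 (14.7 to 21.9) lie close to the floor of the scale, and with log2(signal + 16) their log2 fold changes were 4.01 and 3.33. AT3G09700 lost its call without the intensity trend, at an adjusted p of 0.0512.

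Among the falls, TPS-CIN, a monoterpene synthase, fell by 2.61 on the log2 scale (SE 0.28, adjusted p = 0.000428). SWEET2, a sugar transporter of the vacuole, fell by 2.14 (SE 0.17), and AT5G38710, a proline dehydrogenase, fell by 2.03 (SE 0.18). AT1G70880 and AT4G14060, both of the Bet v I family of small ligand-binding proteins, were also lower: AT1G70880 fell by 2.39 (SE 0.19) and AT4G14060 fell by 1.99 (SE 0.15). AT4G22610, of the lipid transfer protein family, fell by 1.96, and AT2G16005, a protein with a lipid recognition domain, fell by 1.90 from a mean log2 signal of 13.22 ± 0.24 (SD, n = 3) to 11.32 ± 0.16 (SD, n = 3). AT4G04990 at -2.48, AT1G19540 at -2.09 and AT4G37220 at -1.83 completed the 10 largest falls. For each of these 20 genes the 3 lib arrays lay on one side of the 3 wild type arrays. Adjusted p-values ran from 2.18e-05 for AT2G41730 to 0.00418 for AT3G09700. Among the probe sets without a gene name that met the same criteria, the largest log2 fold changes were 3.83 and -2.95.

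Over all 22746 probe sets, 4708 (20.7%) changed, 2364 of them higher and 2344 lower in lib. A change of at least 2-fold was met by 1122 probe sets, 554 higher and 568 lower, of which 652 carry 1 gene name, 438 none and 32 several. At an unadjusted p under 0.05 the count was 7480. The arrays of both genotypes did not overlap for 38.1% of the probe sets, where chance gives 10%. The count of 4708 was 2383 without the intensity trend and 2705 without lib replicate 1. The median log2 fold change over all probe sets was -0.043.

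**Figure D1:**
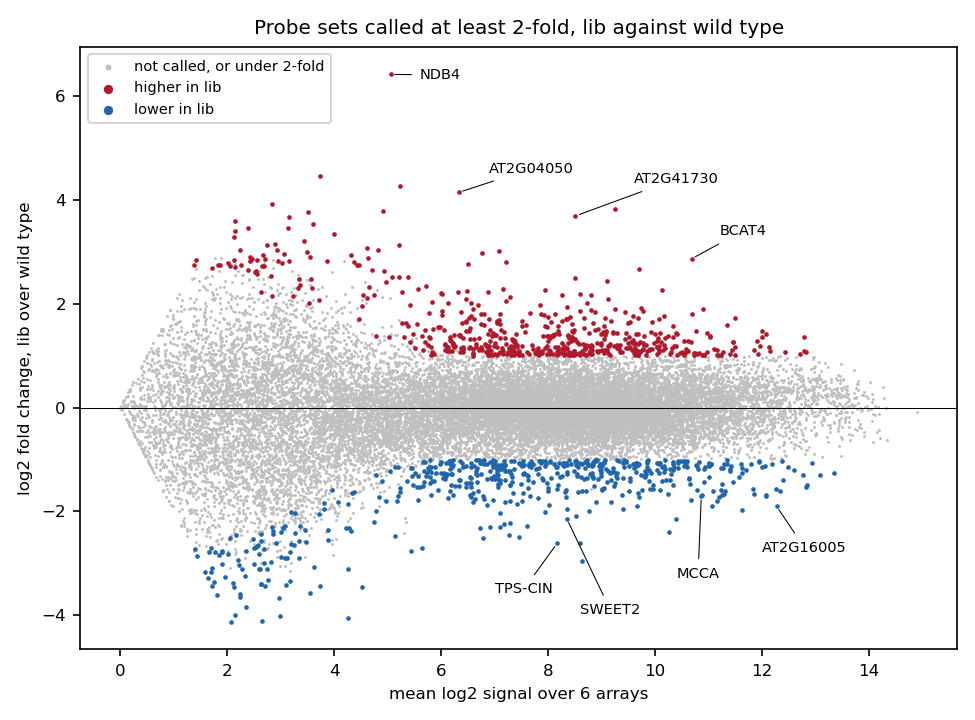
Log2 fold change of each probe set (lib minus wild type) against its mean log2 signal over the 6 arrays. Coloured points are the 554 higher (red) and 568 lower (blue) probe sets with an adjusted p under 0.05 and at least a 2-fold change, grey points are all others, and NDB4 has the largest fold change, 6.41.

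The authors' deposited table gives its own comparison of the same arrays. In the authors' deposited table, a p under 0.05 is given for 5383 probe sets, where 1137 would be expected by chance, and 1142 of them also differ at least 2-fold, 533 higher and 609 lower. These p-values are unadjusted. After Benjamini-Hochberg adjustment of the p-values in the authors' deposited table, 66 probe sets lie under 0.05, 36 of them with a 2-fold change, and the smallest adjusted value is 0.0350. Of the 1142 probe sets in the authors' deposited table, 1011 were also among the 1122 of limma, each in the same direction, and 125 had no limma call at all.

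On the arrays behind all gene groups that follow, the shoot markers LHCB4.1 and RCA were both lower in lib, at a log2 fold change of -0.62. The genes of branched-chain amino acid synthesis did not move together. AT2G31810, a regulatory subunit of acetolactate synthase, the first enzyme common to valine, leucine and isoleucine, fell by 1.02 on the log2 scale (SE 0.13, adjusted p = 0.00114), with signals of 1662 to 2019 in lib and 3303 to 4490 in the wild type. The other members were on the positive side without passing: AT3G23940 (dihydroxyacid dehydratase) at 0.30 (adjusted p = 0.0768), AT3G58610 (ketol-acid reductoisomerase) at 0.19 (adjusted p = 0.253) and ATBCAT-5 (a branched-chain aminotransferase) at 0.18 (adjusted p = 0.177). Thus 1 of the 4 measured genes, from a list of 14, fell and 3 did not pass. When adjusted over the list alone 2 passed, AT2G31810 lower and AT3G23940 higher in lib. The list as a whole had a median of 0.19, a mean of -0.09 and no call by camera (upward, adjusted p = 0.665), and fry gave the opposite direction (adjusted p = 0.923).

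Of 12 measured genes that break down branched-chain amino acids, from a list of 19, 6 were lower in lib and none rose. Both subunits of methylcrotonyl-CoA carboxylase, a mitochondrial enzyme of leucine breakdown, fell: MCCA by 1.70 (SE 0.10, adjusted p = 6.29e-05) and MCCB by 1.12 (SE 0.15, adjusted p = 0.00110). IVD, the isovaleryl-CoA dehydrogenase, fell by 1.12 (SE 0.11), and ETFQO, which passes its electrons to the respiratory chain, fell by 0.90 (SE 0.10). Named after their values were seen, ALDH6B2 and AT2G26800 (hydroxymethylglutaryl-CoA lyase) were lower by smaller amounts, with log2 fold changes of -0.40 and -0.39. Values that did not pass ranged from -0.16 for D2HGDH to 0.46 for AT5G09300, a subunit of the branched-chain ketoacid dehydrogenase (adjusted p = 0.0556), both also named after their values were seen. The list was called downward by camera (median -0.28, adjusted p = 0.0251), with an adjusted p = 0.251 with an estimated correlation. When adjusted over the list alone 7 members passed, 6 of them lower and AT5G09300 higher in lib. The call was also lost with only the probe sets above the median signal (adjusted p = 0.0761) and with ranks (adjusted p = 0.131), and AT2G26800 lost its own call in 8 of 13 settings.

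Among genes of the aspartate-derived amino acids, MGL (methionine gamma-lyase, which degrades methionine and can feed isoleucine synthesis) fell by 1.60 (SE 0.13, adjusted p = 0.000162), and AT4G33150, the bifunctional enzyme that opens lysine breakdown, fell by 0.70 (SE 0.11, adjusted p = 0.00244). AT1G14810 at 0.17, AT1G72810 at 0.03 and the remaining member did not pass. With 2 of 5 genes lower, also when adjusted over the list alone, camera gave no call (downward, adjusted p = 0.160) although fry did (adjusted p = 0.00483). The median was 0.01 and the mean -0.42.

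In aliphatic glucosinolate synthesis, a list of 22 genes, 3 of 4 measured genes rose. Beside BCAT4 (2.86), these were GSTU20, a glutathione transferase of the pathway, at 2.09 (SE 0.12, adjusted p = 6.29e-05), and AT2G31790, a glucosyltransferase of the pathway, at 1.71 (SE 0.17, adjusted p = 0.000340). The rise of GSTU20 was not the only change among the 11 GSTU genes, a family tested after the data were seen. GSTU25 (1.79) and GSTU22 (1.00) also rose, and GSTU28 (-1.13) and GSTU18 (-1.28) fell. Camera gave no call for the family (adjusted p = 0.606). AOP3, which modifies side chains, had signals between 2.46 and 21.7 on the 6 arrays and did not pass (-0.01, SE 0.96, adjusted p = 0.998). The list was called upward (median 1.90, camera adjusted p = 0.00103), with an adjusted p = 0.251 with an estimated correlation, and the same 3 genes passed when adjusted over the list alone. UGT74B1, a glucosyltransferase of the core pathway and the only measured gene of the indolic and shared list, stood at 0.31 (adjusted p = 0.109). With 1 gene, adjustment over the list alone leaves its unadjusted limma p of 0.0309 as it is.

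Of 3 measured regulators of glucosinolate synthesis, from a list of 14, 2 fell. MYC3, a transcription factor of jasmonate signalling that acts with glucosinolate MYB factors, fell by 0.95 (SE 0.11, adjusted p = 0.000590), and AT1G04770, a gene linked to sulfur deficiency, fell by 0.46 (SE 0.14, adjusted p = 0.0428). MYC4 stood at -0.30 (adjusted p = 0.247). The list of 3 was called downward (median -0.46, adjusted p = 0.0251), with an adjusted p = 0.251 with an estimated correlation, and 2 genes passed when adjusted over the list alone. Its call was lost with only the probe sets above the median signal (adjusted p = 0.0761), and AT1G04770 lost its call in 7 of 13 settings. These directions are those of the transcripts, and whether each regulator raises or lowers glucosinolate synthesis was not tested. Of the 4 measured genes for glucosinolate breakdown and transport, PYK10, a beta-glucosidase of ER bodies, was lower (-0.47, SE 0.14, adjusted p = 0.0393, lost in 9 of 13 settings), also when adjusted over the list alone, and the transporters GTR1 (-0.12) and GTR2 (0.09) and the glucosidase BGLU28 (0.26) did not pass; the list had no call (adjusted p = 0.665). The sulfate assimilation genes APS3 (0.26, adjusted p = 0.210) and SIR (0.18, adjusted p = 0.304) did not pass either, and 0 of these 2 passed when adjusted over the list alone.

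**Figure D2:**
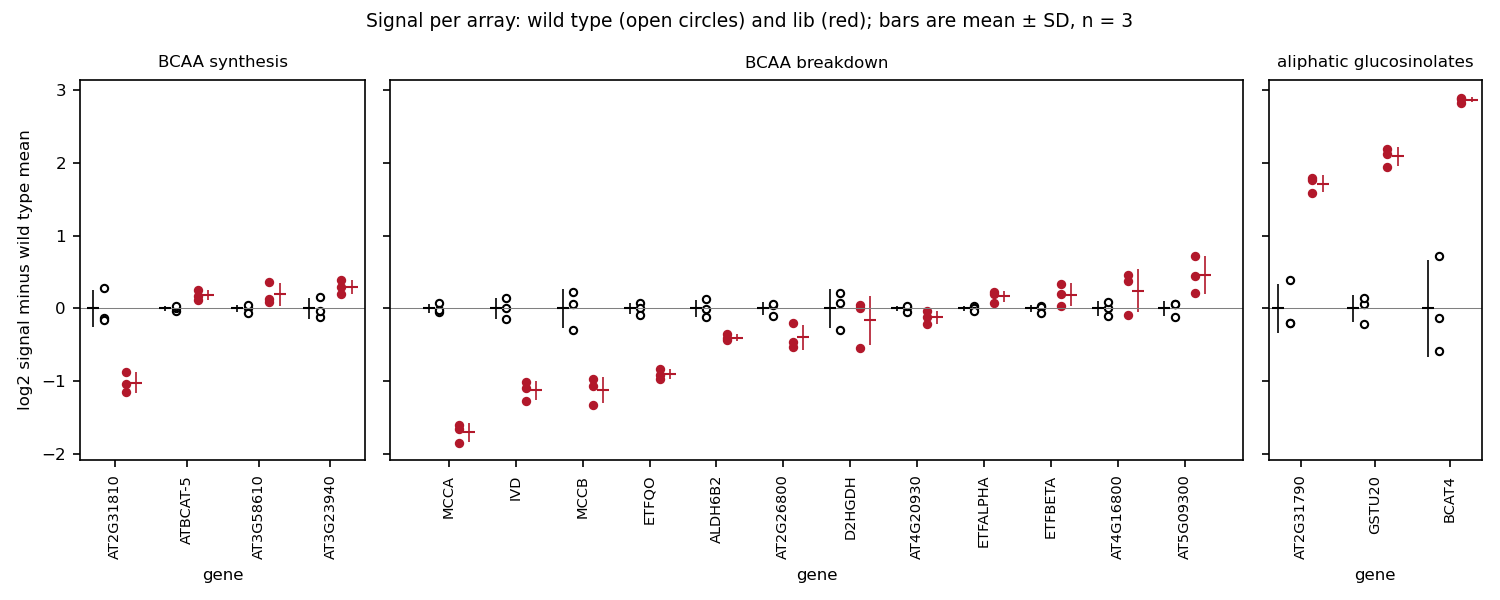
Log2 signal of each array minus the wild type mean of the gene, for the measured genes of branched-chain amino acid (BCAA) synthesis, BCAA breakdown and aliphatic glucosinolate synthesis; open circles are wild type arrays, red circles lib arrays, and the bars give the mean ± SD (n = 3). MCCA lies lowest at -1.70 and BCAT4 highest at 2.86, and AOP3, which is dim on each array, is not drawn.

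Both measured genes of the energy starvation list, which dark and sugar shortage induce, fell: ATL8 by 1.42 (SE 0.14, adjusted p = 0.000295) and AKINBETA1, a subunit of the SnRK1 kinase, by 1.17 (SE 0.12, adjusted p = 0.000325). Both passed when adjusted over the list alone, and with 2 members the list was not tested. The 6 measured genes of the auxin response list, from a list of 15, were all on the low side. WES1, a GH3 enzyme that conjugates auxin, fell by 0.75 (SE 0.12, adjusted p = 0.00246), and LBD16, a transcription factor of lateral root initiation, fell by 0.82 (SE 0.18, adjusted p = 0.0124). LBD29 stood at -0.90 (adjusted p = 0.0589) and IAA29, with dim signals of 21.8 to 49.3, at -0.60 (adjusted p = 0.301). The auxin list was called downward (median -0.70, adjusted p = 0.0251), with an adjusted p = 0.251 with an estimated correlation, and 3 genes passed when adjusted over the list alone. Its call was lost with only the probe sets above the median signal (adjusted p = 0.0765) and without wild type replicate 1 (adjusted p = 0.0811). The 7 genes of the IAA family, tested after the data were seen, did not share this direction. Of these, 2 rose and 0 fell (median 0.10), and camera gave no call (upward, adjusted p = 0.894).

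For jasmonate, PDF1.2 did not pass (0.30, adjusted p = 0.713) and JMT was listed at 0 on the 3 wild type arrays and on lib replicate 2, so no fold is given; 0 of these 2 passed when adjusted over the list alone. Of the abscisic acid and cold genes, COR47, a dehydrin, fell by 0.52 (SE 0.11, adjusted p = 0.0103), while COR15B (-0.47, adjusted p = 0.537) and COR15A (-0.42, adjusted p = 0.867) did not pass. That list had no call (adjusted p = 0.247), and 1 of its 3 genes passed when adjusted over the list alone. In the cell division list AUR2, an Aurora kinase, rose by 0.68 (SE 0.16, adjusted p = 0.0186), and AUR1 (0.22) and PRL, an MCM subunit of the replication helicase (0.28), did not pass. The list of 3 had no call (adjusted p = 0.0739, and 0.251 as the adjusted p with an estimated correlation). It was called with the replicate number as a block (adjusted p = 0.0464) and without wild type replicate 3 (median 0.43, adjusted p = 0.0430). When adjusted over the list alone, 1 gene passed.

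In the list of cytosolic ribosomal proteins fixed beforehand, AT5G02870 rose by 0.36 (SE 0.11, adjusted p = 0.0462) and the other members stood between 0.26 and 0.48 without passing: AT2G19730, PGY1 at 0.39 and AT3G09630. All 4 passed when adjusted over the list alone. This list was called upward (median 0.38, adjusted p = 0.0383), with an adjusted p = 0.251 with an estimated correlation, and its call was lost with quantile normalization (adjusted p = 0.0781), after centring (adjusted p = 0.0709), above the median signal (adjusted p = 0.0761), without lib replicate 1 (adjusted p = 0.0517) and without wild type replicate 1 (adjusted p = 0.0811). AT5G02870 lost its own call in 10 of 13 settings. In the longer list added before any fit, 36 of 63 measured genes rose, none fell, and all 63 had a positive fold change. Examples, chosen after their values were seen, are AT5G67510 at 1.07 (SE 0.13), AT2G20450 at 0.96 (SE 0.12) and AT2G39390 at 0.91 (SE 0.08). The longer list had a median of 0.47 and was called upward (adjusted p = 1.10e-17), with an adjusted p = 0.451 with an estimated correlation.

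Several photosynthesis genes were lower in lib. Of the 4 shoot markers fixed beforehand, LHCB4.1, a light-harvesting protein, fell by 0.62 (SE 0.18, adjusted p = 0.0376) and RCA, Rubisco activase, fell by 0.62 (SE 0.19, adjusted p = 0.0493). PRK (-0.70, adjusted p = 0.276) and SBPASE (-0.28, adjusted p = 0.696) did not pass, 2 genes passed when adjusted over the list alone, and the list had no call (adjusted p = 0.0890). It was called with the replicate number as a block (adjusted p = 0.0464) and without wild type replicate 3 (adjusted p = 0.0483). With an estimated correlation its adjusted p was 0.443. LHCB4.1 lost its call in 6 of 13 settings and RCA in 10. In the longer added list 3 of 9 genes fell. Among them, and named after its value was seen, AT1G32470, an H protein of glycine decarboxylase, fell by 0.94 (SE 0.19, adjusted p = 0.00855). That list was called downward (median -0.62, adjusted p = 0.0287), with an adjusted p = 0.602 with an estimated correlation, and the call was lost without the intensity trend (adjusted p = 0.0559), without lib replicate 2 (median -0.35, adjusted p = 0.0826) and without wild type replicate 1 (median -0.40, adjusted p = 0.140).

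Genes of the chloroplast chromosome, a list chosen after the data were seen, fell in 17 of 69 cases and rose in none. petB fell by 1.07 (SE 0.13, adjusted p = 0.000783), rpl33 by 1.11 (SE 0.14, adjusted p = 0.000832) and psbK by 0.83 (SE 0.11, adjusted p = 0.00109), examples chosen after their values were seen. The list was called downward (median -0.27, adjusted p = 5.88e-05), with an adjusted p = 0.451 with an estimated correlation. Its median was -0.15 without lib replicate 3 (adjusted p = 0.00105) and -0.42 without lib replicate 2 (adjusted p = 3.48e-05). The root hair markers EXPA7 (0.20, adjusted p = 0.444) and EXPA18 (-0.0041, adjusted p = 0.991) did not pass, and 0 of these 2 passed when adjusted over the list alone. PYK10 was also the only measured gene of the list of other root markers, where adjustment over the list alone leaves its unadjusted limma p of 0.00735 as it is. In the extensin family, of which many members are active in root hairs, AT1G26250, named after its value was seen, fell by 1.44 (SE 0.30, adjusted p = 0.00993). The other 7 of 8 genes did not pass, and the list had no call (median -0.63, adjusted p = 0.0548, and 0.602 as the adjusted p with an estimated correlation). It was called in 6 settings: with quantile normalization (adjusted p = 0.0421), after centring (0.0354), with ranks (0.0249), and without lib replicate 1 (0.0116), wild type replicate 1 (0.0383) or wild type replicate 2 (0.0210). Its median was -0.37 without lib replicate 3 and -0.29 without wild type replicate 3. AT1G23720, AT5G06630, AT4G08410 and HRGP1, named here for their probe sets alone, are on probe sets of the type that can cross-hybridise. The estimated correlation within the list was 0.779, so its genes may not give separate measurements.

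**Figure D3:**
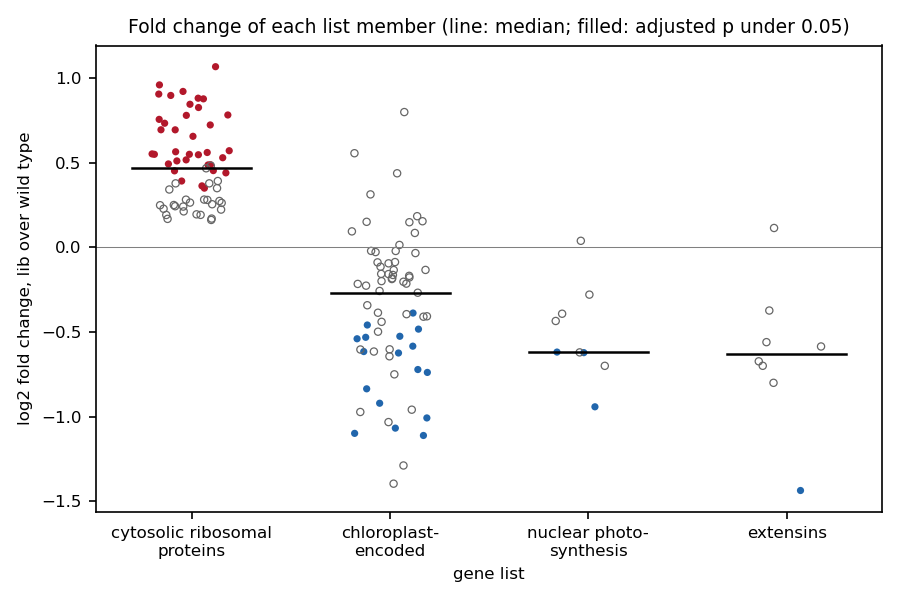
Log2 fold change (lib minus wild type) of each measured gene in 4 added lists, with filled points for an adjusted p under 0.05 (red higher, blue lower), open points for the others and a line at the median. The medians are 0.47 for cytosolic ribosomal proteins, -0.27 for chloroplast-encoded genes, -0.62 for nuclear photosynthesis genes and -0.63 for extensins.

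In all, 5 of the 11 tested lists fixed beforehand were called by camera at the preset correlation, and 0 with an estimated correlation, where 1 list, aliphatic glucosinolate synthesis, had an unadjusted p under 0.05 (0.0260). Fry, which asks whether the genes of a list move on balance one way and not whether they move more than other genes, called 7.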

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

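The background of all probe sets, the chloroplast-encoded list and the gene families were chosen after seeing the data, and 6 lists were added once the annotation was known, before any fit; the other settings were planned. Of 77 genes, those the rule names and all of branched-chain breakdown, 43 were called, and 32 of these kept direction and call in each of up to 13 settings. The other 11 lost the call somewhere (AT3G09700, ALDH6B2, AT2G26800, AT1G04770, PYK10, LBD16, COR47, AUR2, AT5G02870, LHCB4.1 and RCA). The changed probe sets numbered 2383 (1199 higher, 1184 lower) without the intensity trend and 2257 (1183 higher, 1074 lower) at an adjusted p under 0.01. Leaving out an array gave 2705 to 3747 changed (1340 to 1950 higher, 1365 to 1866 lower), 939 to 1129 at least 2-fold and 3 to 7 called lists; fewer arrays leave less power. The lowest counts came without lib replicate 1 for all changes (2705), without lib replicate 3 for 2-fold changes (939) and without wild type replicate 1 for the lists (3). The probe sets above the median signal left 598 2-fold changes and 1 called list, with fewer probe sets tested. Branched-chain breakdown was then not called (median -0.39), nor by ranks (median -0.28), and the cause was not tested. With an estimated correlation 0 lists were called (branched-chain breakdown -0.28, aliphatic glucosinolates 1.90). The unadjusted camera p also rose in fixed lists whose estimated correlation lay below 0. It went from 0.116 to 0.184 for the aspartate-derived amino acids (-0.054) and from 0.665 to 0.683 for branched-chain synthesis (-0.075). Correlation between genes therefore does not alone account for the lost calls, and the rest of the cause was not tested. At an authors' p under 0.01 the overlap with the authors' deposited table was 622, from fewer probe sets.

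The replicate numbers do not pair the arrays: deviations of same-numbered arrays correlated at 0.047, -0.202 and -0.225, and not every array correlated best with its own number. With the number as a block 3442 probe sets changed, 994 at least 2-fold, and 7 of the fixed lists were called, among them shoot markers and cell division (both adjusted p = 0.0464).

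Reversals came in genes and lists without a call, and the cause was not tested. AOP3 was 0.069 with quantile normalization and 0.0043 after centring, and EXPA18 was 0.0098 and 0.0073. For lists, a reversal is one of the direction of the camera test, not of the median. The class III peroxidases went from upward (median -0.0080) to downward with quantile normalization and above the median signal, where the median was 0.013. With array weights D2HGDH was 0.0056 and EXPA18 0.0043. With an array left out, AOP3 ranged from -0.63 to 0.78, EXPA18 from -0.14 to 0.16, D2HGDH from -0.31 to 0.031 and AT1G72810 from -0.059 to 0.097. BGLU28 ranged from -0.34 to 0.65, COR15A from -1.52 to 0.81, SBPASE from -0.54 to 0.0056 and GTR1 from -0.23 to 0.016. The class III peroxidases and the small heat shock proteins then reversed by the direction of their test. Their medians ranged from -0.0036 to 0.12 and from -0.24 to -0.16. The filter on detection calls was not run, and OMR1 had no value. Signals near the floor, as of AOP3, COR15A and JMT, limit what these arrays can show.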

Other observations

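The families, the lists other than those of the 21 and the genes named here were chosen after the data or the annotation had been seen. Of 9 XTH genes, which encode xyloglucan-modifying enzymes, 3 passed: XTH18 rose by 1.71 (SE 0.16, adjusted p = 0.000277), XTH20 by 0.90 and XTH19 by 0.83. Of 10 alpha-expansins EXPA9 rose by 1.15 (SE 0.12, adjusted p = 0.000422) and EXPA15 by 0.45. Among 10 genes of RALF-like signalling peptides RALFL24 rose by 1.49 (SE 0.12), RALFL27 by 1.08, RALFL34 by 0.75 and RALFL31 by 0.72, while 5 were negative without passing, among them RALFL25 at -1.87 (SE 1.01) and RALFL26 at -1.85 (SE 0.91), and the family median was -0.03. Of 26 CYP genes CYP71B37 fell by 1.40 (SE 0.14, adjusted p = 0.000338), CYP71B23 by 1.08 and CYP71B6 by 0.49. None of the 34 families was called by camera after adjustment (XTH 0.0802, EXPA 0.0850, CYP 0.0850, RALFL 0.397), and with an estimated correlation the adjusted p was 0.638 for XTH, EXPA and CYP and 0.812 for RALFL. The 12 genes above that rose or fell kept their sign and call under both other scalings.

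Among 11 genes for proteins that accompany myrosinase and ER bodies 4 fell and 1 rose: NAI2 fell by 0.78 (SE 0.15, adjusted p = 0.00621), the jacalin-type lectins JAL33 and JAL34 fell by 0.62 and 0.60, and PYK10 was at -0.47 (not called after centring, adjusted p = 0.0736), while AT1G52050 rose by 1.29 (SE 0.28, adjusted p = 0.0123). The list of 11 was not called (median -0.60, adjusted p = 0.238). Of 41 class III peroxidases 5 rose, the most AT5G24070 at 1.63 (SE 0.37) and AT1G44970 at 1.09 (SE 0.19), and 4 fell, the most AT5G14130 at -1.04 and AT5G39580 at -0.96; the median was -0.0080, the mean -0.05 and camera gave no call (upward, adjusted p = 0.890). Of 5 small heat shock proteins and chaperones AT5G51440 rose by 0.37 (adjusted p = 0.0421), and the list was not called (median -0.21, adjusted p = 0.890).

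The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The split by genotype called 4708 probe sets, 1 of the 10 splits to reach that number, and the highest other split called 0.

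Of the tests that follow, those on green tissue and on the unseen members of the mitochondrial list were chosen only after the result was seen. The cytosolic ribosomal protein genes had a median log2 fold change of 0.47 over 63 genes. Scaling that depends on brightness is argued against by 10000 random lists matched on mean signal, of which the middle 95% had medians from -0.076 to 0.236. These random lists leave out correlation between genes. With quantile normalization the median of the 63 genes was 0.38, and 31 of their 36 calls held both with it and after centring. One array does not set the shift: the lowest median with an array left out was 0.39, without lib replicate 3. An effect of the mutation on these genes may be the cause and was not tested further. The correlation estimated among the 63 genes was 0.404, so they varied together between samples. With that estimate the list was not called by camera (adjusted p = 0.451).

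Of 9 nuclear photosynthesis genes (median -0.62) 3 fell, and of 69 chloroplast-encoded genes (median -0.27) 17 fell; both medians lay below the middle 95% of matched random lists (lower bounds -0.38 and -0.18), which leave out correlation between genes, and neither list was called with an estimated correlation (adjusted p = 0.602 and 0.451). Relative to the wild type mean, the median of the photosynthesis genes was -0.44, -0.85 and -0.41 on the lib arrays and 0.40, 0.01 and -0.34 on the wild type arrays, and it was -0.35 without lib replicate 2 and -0.40 without wild type replicate 1; the chloroplast-encoded median was -0.15 without lib replicate 3 and -0.42 without lib replicate 2. Less green tissue in the lib arrays may account for this, and the labels, which name both seedlings and roots, leave room for it. If so the photosynthesis genes should fall alike, provided that all 9 are expressed in green tissue alone, which was not tested. Cochran's Q, computed first, was 27.3 over the 9 genes (8 expected if alike) and 4.86 without AT1G11860 (7 expected). In the test used in its place 1 of 9 lay more than 3 SE from their median, AT1G11860 at 0.04 (SE 0.11), a subunit of glycine decarboxylase. Since this rests on that gene alone, and AT1G32470 of the same enzyme fell by 0.94 (SE 0.19), the most of the 9, less green tissue and lower expression within it cannot be told apart.

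NDB4, AT2G04050, AT2G41730, AT2G21640, AT1G24095 and AT2G32020, all seen among the 30 largest rises beforehand, belong to genes known to respond to mitochondrial dysfunction. With AT5G09570 (1.86, adjusted p = 0.0205) 7 of 10 measured members of such a list rose, and the same 7 still passed with log2(signal + 16), which argues against noise near the floor as the cause of these rises (adjusted p at most 0.0123), though 6 of them were listed because they had risen, so it does not show that the list as a whole rose. A mitochondrial dysfunction response in lib may be at work, but of the 4 members not seen before the list was written only AT5G09570 rose, against 10.3% of other genes (one-sided Fisher's exact test, p = 0.354). AT1G05060 (-0.34), AT2G04070 (0.19) and AT5G43450 (0.04) did not pass. The 4 unseen members are too few to decide.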
